A study of Mus musculus with 2 samples.

How the data were processed

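ChIP-Seq libraries were made from R1/E mouse ES cells carrying BAC-tagged TOBF1, 1 with an anti-GFP antibody and 1 input without antibody, per the labels. Reads were handled with cutadapt, Bowtie2, MACS2 and bedtools on the mm10 build, per the submitters' processing notes, which give no versions, order or settings. Whether the input served as control of the peak call, which reads were kept at repeated sequences, and how deeply the libraries were sequenced are not given in the sources used here. The deposited peak list gives chromosome, start, end, name and a score per peak. The deposited score was read as −log10 of a q-value, because no value was negative and the lowest, 1.30, was just above −log10 of 0.05. A score depends on sequencing depth and on the local background, so scores were used only within this list, to rank and filter peaks and to compare medians between groups of peaks, whose local background can differ. Peak names ran from 1 to 12181 without gaps, and positions are given from 1 as a genome browser shows them.

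Genes came from a RefSeq table of the GRCm38.p6 assembly, whose chromosome positions are those of mm10. The table used here gives the start, end and type of each gene but no strand, transcripts or exons, and no genome sequence was used. The planned tests at transcription start sites were therefore made at both ends of each protein-coding gene, 1 of which is its start. Classes of exons and untranslated regions, motif tests, and draws matched on GC or CpG content were planned and not run. The 169 peaks on scaffolds outside the chromosomes were left out of the comparisons.

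A peak was counted at a gene end when its midpoint lay within 1 kb of it. Expected shares came from 1000 shuffles of the peaks within their chromosome, between the lowest and the highest position of any peak or gene on it. The planned exclusion of assembly gaps was not made, because gap positions were not used here. P-values of shuffles and of random lists are empirical permutation p-values, two-sided, and those of shuffles have 0.002 as the smallest possible. Intervals on shares are exact (Clopper-Pearson, 95%) and cover counting error only. Score medians were compared with 100000 permutations. The 19 gene lists (634 entries, of which 633 matched a protein-coding gene; Neat1 did not) were written before the data were examined and tested with Fisher's exact test against all other protein-coding genes. P-values were adjusted by Benjamini-Hochberg over the lists, with a threshold of 0.05. Lists share some members, such as 2 genes in the core pluripotency and signalling lists. The search within 10 kb used 10000 random lists drawn from 20 bins of gene length.

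Genes were named by a rule set before the data were examined. It took Bclaf3 and Pou5f1, the 15 genes with the highest scores at their ends, the 5 highest peaks over 10 kb from any gene end, up to 4 members per list with a peak at an end and up to 10 for the core pluripotency list. Genes named outside it are marked in the text, and some genes that the rule takes are not reported here. Alternatives were a stricter threshold (peaks at or above the median score), windows of 500 bp and 5 kb, any overlap with the window, merged peaks and leaving out chromosome X. Added after the data were seen were a shift of each peak by 20 to 500 kb, leaving out the tagged-gene region or dense regions (6 or more peaks at gaps up to 10 kb), genes of every type, and random lists matched on gene length. The methods were tested on simulated data. Of 200 peaks moved to gene ends, a gain of 193.75 was recovered where 193.965 was put in. Those peaks were placed within 500 bp of an end and counted within 1 kb, so this checks the counting only. In 20 simulations without an effect, 1.58% of list tests by Fisher's exact test and 0.789% by length-matched draws lay under an unadjusted 0.05. Genes were drawn there independently, without shared or grouped peaks, so these rates need not hold for the real peaks. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.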

Results

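Binding of TOBF1 to chromatin was measured by ChIP-Seq in mouse embryonic stem (ES) cells of the R1/E line, grown in serum with LIF, the cytokine that keeps such cells undifferentiated. TOBF1 is the protein of A830080D01Rik, listed by RefSeq under the symbol Bclaf3. The cells carried a tagged copy of this gene on a bacterial artificial chromosome (BAC), a large piece of mouse genomic DNA, and the tagged protein was precipitated with an antibody against GFP after crosslinking with formaldehyde and DSG. The series holds 1 TOBF1 library, for which a peak list was analysed, and 1 input library made without antibody, for which no file was used here. With 1 library per group, no value below has a replicate error, and the tests compare peak positions with random positions, gene lists with other genes, or groups of peaks within the list. The list held 12181 peaks with a median width of 216 bp (quartiles 170 and 286 bp). Their scores, the peak caller's own values and read here as −log10 of a q-value, ran from 1.30 to 216.1 with a median of 9.97. The number of reads behind the peaks is unknown. Of these peaks, 12012 lay on chromosomes 1 to 19, X and Y of the mm10 build and entered the comparisons.

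The first comparison asked which genes TOBF1 peaks lay next to. Genes listed for the pluripotency network, which includes factors that hold ES cells in the undifferentiated state, stood out among the 19 gene lists. So did genes of cytoplasmic ribosomal proteins. No expression values and no precipitation from untagged cells were used here. For every list, TOBF1 binding therefore cannot be told apart from signal that active genes give with any antibody. Within 1 kb of either end of the gene, 13 of 40 core pluripotency genes had a peak (32.5%, exact 95% interval 18.6 to 49.1%), against 2.62% of all other protein-coding genes. Cytoplasmic ribosomal protein genes had such a peak in 33 of 74 cases (44.6%, interval 33.0 to 56.6%). The list named LIF, BMP and Wnt signalling, which also holds genes of the ERK pathway such as Dusp6, followed with 5 of 30 (16.7%). Splicing factors had 6 of 54 (11.1%). In Fisher's exact test (two-sided, Benjamini-Hochberg over the 19 lists) these 4 lists were enriched 12.4-fold (adjusted p = 1.84e-10), 17.6-fold (adjusted p = 3.93e-31), 6.28-fold (adjusted p = 0.00696) and 4.19-fold (adjusted p = 0.0147). No list was depleted, and 5 lists lay under an unadjusted p of 0.05. With only the peaks at or above the median score, 0 of the 19 lists passed the adjusted threshold and 3 lay under an unadjusted p of 0.05. These were core pluripotency genes (8.19-fold, adjusted p = 0.0573), ribosomal protein genes (5.93-fold, adjusted p = 0.0573) and splicing factors (6.06-fold, adjusted p = 0.0873), all by Fisher's exact test, while LIF, BMP and Wnt genes fell to 0 of 30. Within 500 bp of an end, the signalling list (3 of 30, 6.68-fold, adjusted p = 0.0646) and the splicing factors (3 of 54, 3.71-fold, adjusted p = 0.228) did not pass Fisher's exact test.

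Among the core pluripotency genes with a peak at a gene end, Rif1, a telomere and replication-timing factor, had the highest score (55.1), followed by the F-box gene Fbxo15 (21.3), the Nodal co-receptor gene Tdgf1 (10.5), the corepressor gene Trim28 (9.91) and Zfp42, which encodes the ES cell marker Rex1 (8.93). Dppa4 (8.41), Fgf4 (7.61), Utf1 (6.91), Dppa2 (6.63) and Zscan10 (6.38) came next. Pou5f1, which encodes the pluripotency factor Oct4, had a peak 904 bp from its end with a score of 6.11. The signalling genes with the highest scores were Smad7, an inhibitor of TGF-beta and BMP signalling (5.21), Dusp6, a phosphatase of the ERK pathway (5.11), Klf4 (3.25) and Etv4 (3.10). Spry4 (3.02), named outside the rule, was the remaining one. The Wnt genes Lef1, Tcf7l1 and Axin2 of this list had no peak at an end. Ribosomal protein genes with high scores included Rps12 (20.1), Rps20 (10.2) and Rpl11 (10.1), and the highest scores among splicing factors were at Hnrnpa2b1 (14.3), Hnrnpa3 (10.4), Prpf31 (10.3) and Hnrnpa1 (9.59).

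The other 15 lists did not pass the test at gene ends. Immediate early and stress genes had 3 of 30 members with a peak, namely Klf6, Hsp90ab1 and Ier2 (Fisher's exact test, adjusted p = 0.172). There were 2 of 48 among cell cycle and DNA replication genes (Bub1b and Rfc4), and 1 each among 30 DNA repair genes (Xrcc5), 35 chromatin regulators (Eed), 18 neural genes (Map2) and 44 oxidative phosphorylation genes (Cox7c). None of the 56 developmental regulators bound by PRC2, 32 liver genes, 26 adult blood and immune genes, 21 aminoacyl-tRNA synthetase genes, 20 germline genes, 20 endoderm genes, 19 paraspeckle genes, 18 mesoderm genes or 18 trophectoderm genes had one. For the PRC2 list the exact 95% interval reached up to 6.38%, so a share at the level of other genes was not excluded.

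A wider search, chosen after the data were seen, counted a peak anywhere in a gene or within 10 kb of it and compared each list with 10000 random lists of the same gene lengths. By this measure 36 of the 40 core pluripotency genes had a peak, where random lists gave 7.49 (4.80-fold, exact 95% interval of the share 76.3 to 97.2%). The 4 without one were Lefty1, Prdm14, Stat3 and Tcl1. Ribosomal protein genes had a peak in 49 of 74 cases (6.32-fold), LIF, BMP and Wnt genes in 18 of 30 (2.38-fold) and splicing factors in 25 of 54 (2.74-fold). For these 4 lists the adjusted permutation p was 9.50e-04, from the smallest p that the draws can give (2.00e-04). Paraspeckle genes, whose products assemble a nuclear body around the RNA Neat1, had a peak in 10 of 19 cases (2.68-fold, adjusted permutation p = 0.0114), among them Rbm14 (score 59.1), Fam98a (36.4) and Taf15 (30.4). With only the peaks at or above the median score, splicing factors (9 of 54, 1.87-fold, adjusted permutation p = 0.356) and paraspeckle genes (4 of 19, 1.95-fold, adjusted permutation p = 0.749) no longer passed. Core pluripotency genes (28 of 40, 6.51-fold), ribosomal protein genes (16 of 74, 4.56-fold) and LIF, BMP and Wnt genes (14 of 30, 3.05-fold) still passed. Within 50 kb, paraspeckle genes also lost their call (11 of 19, 1.37-fold, adjusted permutation p = 0.416).

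**Figure D1:**
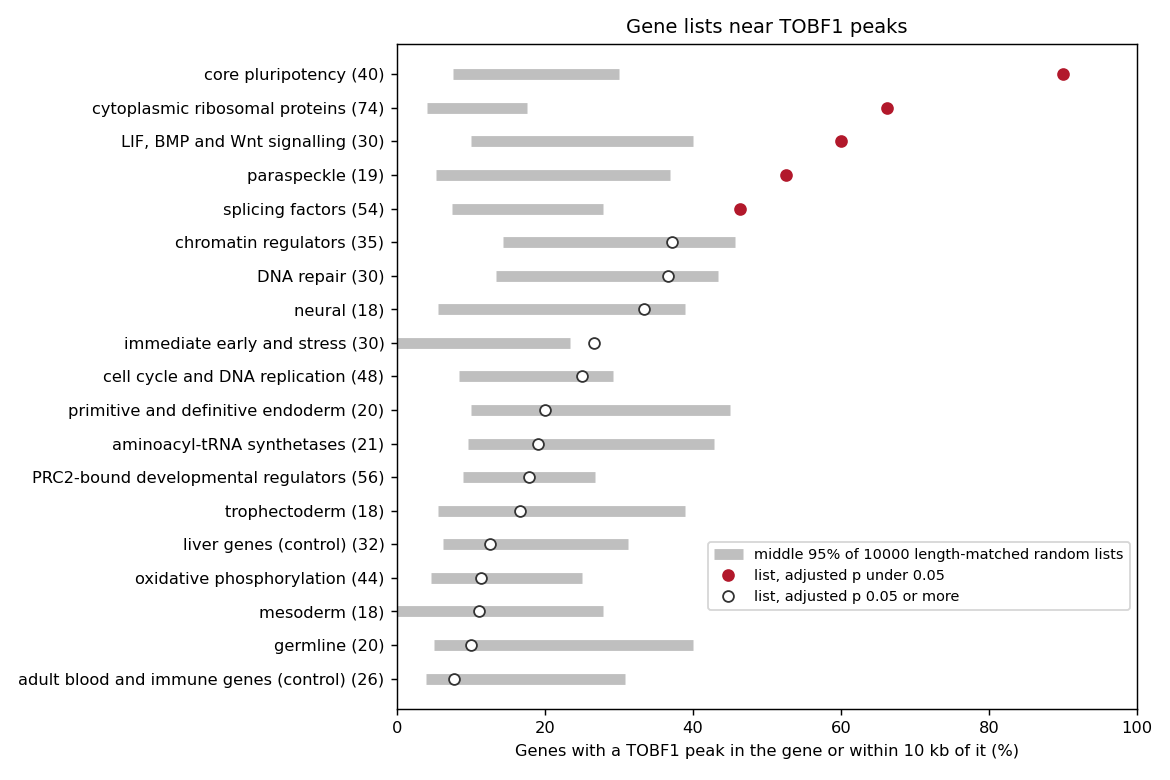
Share of the genes in each list with a TOBF1 peak in the gene or within 10 kb of it, in percent, with the number of genes in parentheses; grey bars span the middle 95% of 10000 random lists of the same gene lengths. Filled points are the 5 lists with an adjusted p under 0.05, from 90.0% of core pluripotency genes to 46.3% of splicing factors.

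Lists of other cell types lay at the level of random lists in this wider search. Liver genes had a peak in 4 of 32 cases where random lists gave 5.64, adult blood and immune genes in 2 of 26 (3.96), germline genes in 2 of 20 (3.99), mesoderm genes in 2 of 18 (2.36), endoderm genes in 4 of 20 (5.54), trophectoderm genes in 3 of 18 (3.30) and PRC2-bound regulators in 10 of 56 (9.94). Neural genes (6 of 18 against 3.59), DNA repair genes (11 of 30 against 7.83), chromatin regulators (13 of 35 against 10.3), cell cycle genes (12 of 48 against 8.64) and immediate early genes (8 of 30 against 3.40) lay above the random mean without passing the adjusted threshold. Oxidative phosphorylation genes (5 of 44 against 5.92) and aminoacyl-tRNA synthetase genes (4 of 21 against 4.85) lay below it, also without passing. Random lists were matched on gene length, not on expression. The contrast with lists of other cell types therefore does not separate TOBF1 binding from signal at active genes.

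Within 10 kb, core pluripotency genes lay next to stronger peaks than ribosomal protein genes did. The median score of the highest peak was 16.5 over 35 distinct peaks at pluripotency genes and 8.75 over 48 at ribosomal protein genes, a difference of 7.78 (permutation test, two-sided, p = 1.00e-04). The highest peak favours long genes, and the median gene length was 9717 bp in the pluripotency list and 3206 bp in the ribosomal one. Over the 23 pluripotency genes no longer than the longest ribosomal protein gene the difference was 5.27 (permutation p = 0.00179), and over all peaks near each list, rather than the highest, it was 1.80 (permutation p = 0.00498). The highest scores of the pluripotency list were at Klf2 (80.2), Otx2 (78.7), Mycn (59.4), Tfcp2l1 (58.6) and Tet2 (56.5), followed by Rif1 (55.1), Jarid2 (49.3), Dppa3 (31.7), Sox2 (30.4) and Tbx3 (28.4). Lef1, a transcription factor of the Wnt pathway (87.7), Il6st, which encodes the shared receptor chain gp130 (76.8), Lgr5 (70.1), Tcf7l1 (41.9), Id3 (39.9) and the LIF receptor gene Lifr (37.5) led the signalling list. Rps19 had the highest score among ribosomal protein genes (103.2), with Rplp1 next (30.5), and Hnrnpr (54.7) and Hnrnpd (28.8) led the splicing factors.

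At Pou5f1 (chromosome 17, 35506032 to 35510777) there were 5 peaks within 20 kb of the gene. Those below the lower end lay 15.5 kb, 1.94 kb and 0.904 kb away, with scores of 16.6, 11.5 and 6.11; another lay inside the gene (2.00) and another 3.55 kb above the upper end (4.91). Sox2 (chromosome 3, 34649995 to 34652461) had a peak 3.55 kb below the gene (34646307 to 34646578, score 30.4) and another 1.53 kb above it (score 16.8). Nanog (chromosome 6, 122707489 to 122714633) had peaks 4.85 kb and 4.49 kb below the gene, with scores of 16.5 and 5.71. At Zfp42 (chromosome 8, 43295067 to 43307009) 15 peaks lay between 43288505 and 43306948, the strongest 5.49 kb below the gene (score 22.9), and at Esrrb 11 peaks lay in the gene or within 10 kb of it. The 15 peaks at Zfp42 and 6 of those at Esrrb form dense regions as defined above, for which raised signal whatever the antibody was not filtered out. Sox2, Nanog, Esrrb and the genes named from the wider search were chosen after their values were seen. Exons, introns and untranslated regions were not annotated here.

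**Figure D2:**
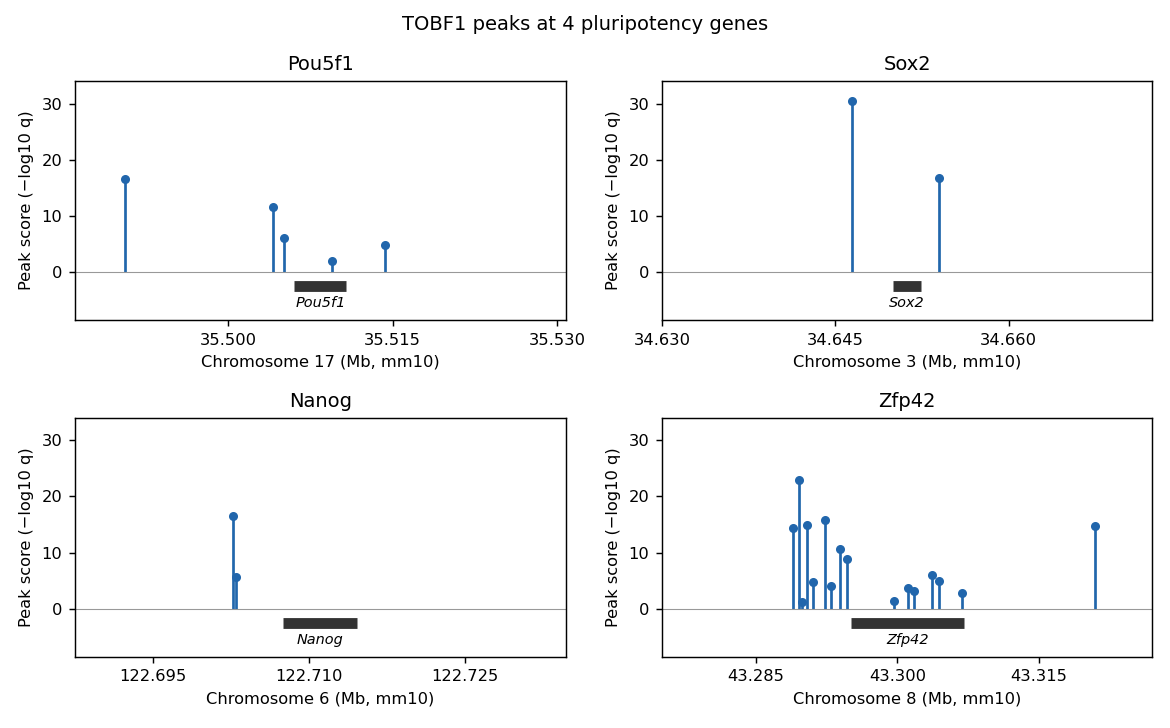
TOBF1 peaks at Pou5f1, Sox2, Nanog and Zfp42: each stem is 1 peak at its midpoint (horizontal axis, position in Mb, mm10), its height is the peak score (−log10 q), and the dark bar is the gene. The highest stems are at Sox2 (30.4) and Zfp42 (22.9), and Zfp42 has the most peaks.

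The strongest peak at the end of any protein-coding gene lay 175 bp from Mobp, a gene of myelin (chromosome 9, 120149407 to 120149726, score 137.7). It was followed by Gm33153 (99.7), a peak shared by the neighbours Dido1 and Gid8 (91.2), Upp1, which encodes a uridine phosphorylase (86.2), Aspm, a gene of the mitotic spindle (73.3), Insyn2b (65.9), Gm6818 (65.4) and Ifitm2 (58.9). Rif1 (55.1), the casein gene Csn3 (51.7), a peak shared by Ugt2a1 and Ugt2a2 (49.6) and Epc1 (48.4) were also among the 15 highest. The highest peak of the whole list was on chromosome 13 (6922334 to 6922744, score 216.1), 273.5 kb from the nearest gene, Pfkp. Among peaks over 10 kb from every protein-coding gene end, the next were inside Abca4 on chromosome 3 (122145325 to 122145804, score 211.6), inside Sptlc2 on chromosome 12 (87317965 to 87318369, score 158.4), 15.4 kb from Vwc2 on chromosome 11 (11098283 to 11098699, score 150.8) and inside Tnfsf11 on chromosome 14 (78288941 to 78289448, score 147.9).

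The second comparison asked where peaks lay relative to genes in general. Peaks were found near gene ends more often than random positions, although most lay far from them. Of the 12012 peaks, 653 lay within 1 kb of the end of a protein-coding gene (5.44%, exact 95% interval 5.04 to 5.86%), against 3.0% ± 0.153 (SD over 1000 shuffles within chromosomes), a 1.81-fold excess. Peaks 1 to 5 kb outside a gene made up 7.21% against 4.28% in the shuffles (1.68-fold), those inside a gene 39.6% against 38.1% (1.04-fold), and intergenic ones 47.8% against 54.7% (0.874-fold). Each of these had a permutation p = 0.002, the smallest that 1000 shuffles can give, also after adjustment over the classes. A total of 8481 peaks (70.6%, against 79.1% in the shuffles) lay over 10 kb from every protein-coding gene end. The median distance to the nearest end was 28.4 kb, against 50.6 kb in the shuffles. Of 21887 protein-coding genes, 585 (2.67%) had a peak within 1 kb of an end, and 4730 (21.6%) had one in the gene or within 10 kb. The share inside genes turned to a deficit when each peak was moved by only 20 to 500 kb (39.6% against 42.1%), and with peaks at or above the median score the share at gene ends, 3.32%, no longer differed from the shuffles (permutation p = 0.16).

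Peaks at gene ends were weaker than the others. Their median score was 7.12 over 653 peaks, against 10.2 over the other 11359 (permutation test, two-sided, p = 1.00e-05, the smallest that 100000 permutations can give). In the lowest quartile of scores 8.76% of peaks lay at a gene end (exact 95% interval 7.77 to 9.83%), in the second 6.36%, in the third 4.13% and in the highest 2.50% (1.97 to 3.12%). The lowest and the highest quartile differed in Fisher's exact test (odds ratio 3.75, two-sided p = 5.73e-27). The highest quartile did not differ from the shuffles (2.99%, adjusted permutation p = 0.13), and fell below them once peaks in dense regions were left out (2.29% against 3.0%, adjusted p = 0.0293).

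**Figure D3:**
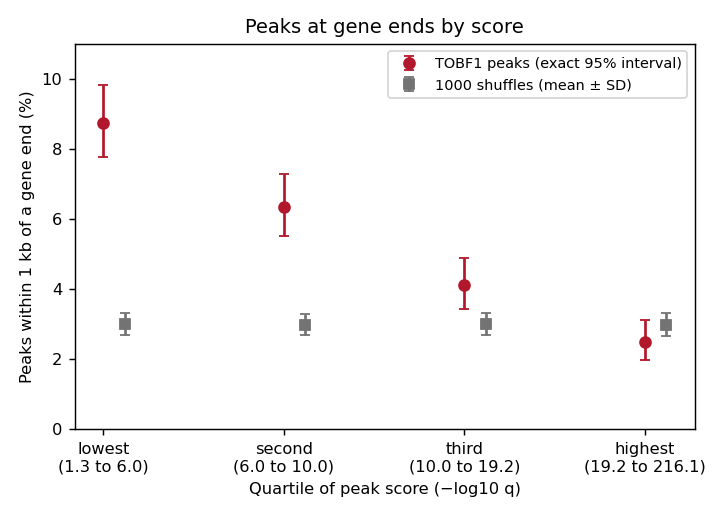
Share of peaks within 1 kb of a protein-coding gene end, in percent, by quartile of the peak score (−log10 q). Red points are the peaks with exact 95% intervals and grey squares the mean ± SD of 1000 shuffles; the share falls from 8.76% in the lowest quartile to 2.50% in the highest, while the shuffles stay near 3.0%.

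Peaks also came in groups. Of all peaks, 31.2% had another peak within 10 kb, against 9.05% ± 0.348 (SD) in the shuffles (permutation p = 0.002), and 24.1% had one within 5 kb, against 4.64%. Peaks were not merged for this, so pieces of 1 enriched stretch can count as neighbours. Merging peaks within 1 kb would leave 11149 of the 12181, and grouping was not tested on merged peaks. There were 64 dense regions on the chromosomes, in which 6 or more peaks followed each other at gaps of up to 10 kb, and they held 769 peaks (6.40%). Regions of repeated sequence, or with high signal whatever the antibody, were not filtered out here and can be among them. Without these regions 26.5% of peaks still had another within 10 kb, against 8.58% in shuffles of the same number.

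The dense region with the most peaks lay around the gene of the tagged protein itself. On chromosome X, 168 peaks filled a region of 194.9 kb (159517409 to 159712350) that holds all of Bclaf3 (159532642 to 159593081) and part of Sh3kbp1, an adaptor of receptor endocytosis. They were 37.5% of the 448 peaks on X and covered 75.6% of the region's length, and 91.7% of Bclaf3. The density was 8.62 peaks per 10 kb inside the region and 0.0164 on the rest of X, and the next peaks lay 1031 kb below and 335 kb above. The 10 widest peaks of the whole list were all in this region, the widest spanning 7027 bp inside Bclaf3 (159559424 to 159566450, score 48.8). Leaving the region out changed the share of peaks at gene ends to 5.49%.

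**Figure D4:**
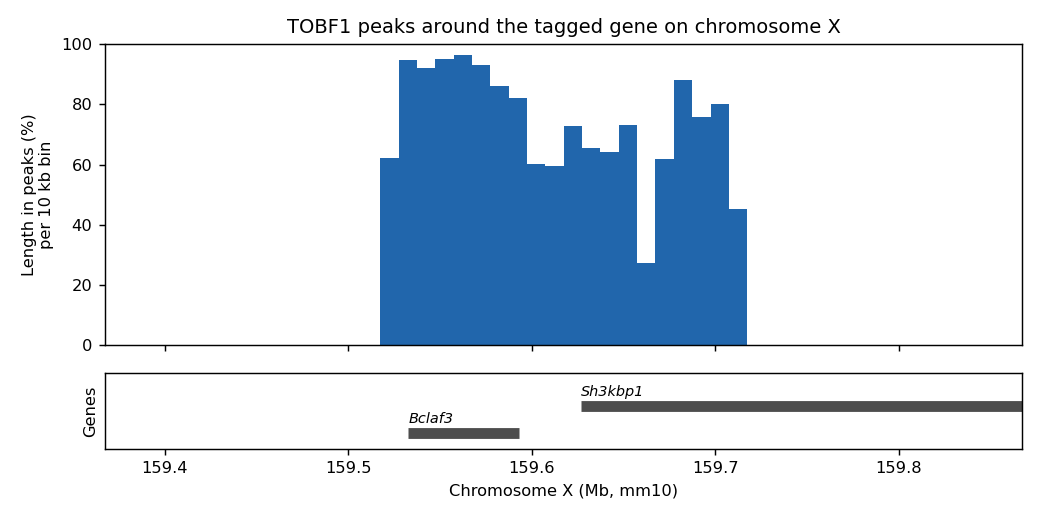
Share of each 10 kb bin covered by TOBF1 peaks (vertical axis, percent) along chromosome X (horizontal axis, Mb, mm10), with the spans of Bclaf3 and Sh3kbp1 below. Peaks fill the region from 159517409 to 159712350 and none lie in the flanks shown.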

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

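The test of pseudogenes and the test of score quartiles without ribosomal protein, histone and snoRNA genes were set before their results were seen; the other tests in this part were chosen afterwards. Outside the chromosomes, in data that no comparison used, 169 peaks lay on 17 scaffolds, 60 of them on Un_JH584304 and 28 on Un_GL456383.

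Peaks filled 194.9 kb around the tagged gene on chromosome X. Binding at separate sites would leave parts of the region like the rest of X. The lowest 20 kb bin inside had 44.5% of its length in peaks, while the highest bin elsewhere on X had 3.64%. This argues against separate sites as the whole cause. The region was picked as a run of peaks, so every bin had to hold some, though not this much. High cover also occurred elsewhere: a dense region on chromosome 8 (20321633 to 20376657) had 46.0% of its length in peaks, against 75.6% for the tagged region. Extra copies of the locus, such as those of the BAC, may account for the filled block, since they predict cover of genes and gaps between genes alike. Whether the peak call used the input, which the labels give the same construct, is not stated, so it stays open how such copies would pass a control. No biological explanation was tested.

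Ribosomal protein genes had peaks at their ends in 44.6% of cases. Reads shared with their pseudogenes would put peaks at those copies too, but 3 of 318 ribosomal protein pseudogenes had one (0.943%, exact 95% interval 0.195 to 2.73%), against 1.20% of other pseudogenes (Fisher's exact test, two-sided, p = 1). Signal that strongly transcribed genes give with any antibody could also produce such peaks, and it cannot be told apart from binding of TOBF1, because no precipitation from untagged cells and no expression values were used here. Histone genes with the symbols H1f, H2ac, H2bc, H3c and H4c, most of which dividing cells express strongly, had a peak at an end in 85.1% of cases. That share goes with that explanation, while 1 of 44 oxidative phosphorylation genes (2.27%), also strongly expressed, goes against it. No biological explanation was tested.

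Weak peaks lay at gene ends more often than strong ones. Positions drawn evenly over each chromosome do not account for all of the weak ones, since 8.76% of the lowest score quartile lay at a gene end against 3.02% in the shuffles. Most of that quartile lay away from gene ends, and the test does not tell whether those peaks are chance positions. Peaks at ribosomal protein, histone and snoRNA genes make up part of the trend but not all of it. Without those 191 peaks the share in the lowest quartile fell from 8.76% to 6.12%, against 3.01% in the shuffles. It still lay above the 2.43% of the highest quartile (Fisher's exact test, two-sided, p = 1.39e-12). Weaker or indirect contact at gene ends, which the DSG crosslinker might capture, was not tested. Signal that active genes give with any antibody could also lie at gene ends and was not tested. Evenly drawn positions cannot tell such signal apart from binding of TOBF1.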

How the results depend on the processing

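The local shift, the removal of the tagged or dense regions, matched draws, the score comparison of lists and all of the search within 10 kb were chosen after the data were seen. Of the alternatives to the main tests, 22 kept the direction and the side of the threshold, 3 lost the call and 1 turned the direction; of those to counts without a test, 14 stayed within 1.5 times and 7 did not. With peaks at or above the median score (6150 by the median of all peaks; the tests used the 6021 at or above the median on chromosomes), the share at gene ends was 3.32% and no longer passed, as for the same class among the genomic classes, and the share inside genes was 39.2% (adjusted permutation p = 0.115). Of the lists, 0 passed at gene ends (3 under an unadjusted p of 0.05 in Fisher's exact test) and 3 within 10 kb, and 203 genes had a peak at an end. LIF, BMP and Wnt genes fell to 0 of 30 where 0.279 were expected, too few to give a direction. The fold of ribosomal protein genes fell from 17.6 to 5.93 and that of core pluripotency genes from 12.4 to 8.19. Fewer peaks were tested there; whether weaker peaks are less specific was not tested. A window of 500 bp left 330 genes and 2 lists, and a window of 5 kb gave 1964 genes, as the size of the window sets these counts. The share inside genes was 39.6% against 42.1% under the local shift, a deficit; the cause was not tested. For single lists, histone genes and list scores, 52 alternatives kept the call, 8 lost it and 1, the 0 of 30 LIF, BMP and Wnt genes, was counted as turned. Draws matched on GC or CpG content, the most upstream start of each gene, exon classes and all motif tests were not run, since they need sequence or transcripts. No paired analysis was possible because there is 1 library per group. Paraspeckle genes lost their call with a window of 50 kb (11 of 19, adjusted permutation p = 0.416). The depth of the libraries is unknown, so a gene without a peak is not shown to lack TOBF1.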

Other observations

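All tests in this part were chosen after the data were seen. Histone genes were taken by the symbols H1f, H2ac, H2bc, H3c and H4c, and histone genes with other symbols were not counted. The genes so taken had peaks at their ends in a higher share of cases than any of the 19 lists, a difference that was not tested. Of 67 such genes, 57 had one (85.1%, exact 95% interval 74.3 to 92.6%), against 2.42% of other protein-coding genes (35.2-fold, Fisher's exact test, two-sided, p = 2.72e-80). In the cluster on chromosome 13 it was 48 of 53 and in that on chromosome 3 it was 9 of 10, together 57 of 63 (90.5%, interval 80.4 to 96.4%). The 4 counted genes outside these clusters, the separate H1 variants H1f0, H1f7, H1f8 and H1f10, had none. Of 142 other protein-coding genes within 1 Mb of them, 7 had a peak (4.93%, interval 2.00 to 9.89%, Fisher's exact test, two-sided, p = 1.20e-35). Those neighbours were not matched on activity or spacing, and non-coding genes were left out. The comparison therefore does not separate the histone genes from an active stretch around them. The 57 genes had only 39 distinct highest peaks, since neighbouring genes share them. Fisher's exact test counts genes as independent, so the p-values in this paragraph overstate the evidence. The scores of these 39 peaks were modest, with a median of 7.67 and a maximum of 22.6. With peaks at or above the median score 12 of the 67 genes had one, and without dense regions 28.

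Genes of small RNAs were also near peaks. Within 1 kb of a tRNA gene end there were 37 peaks where shuffles gave 3.46 (10.7-fold), and 54 of 408 tRNA genes had one, 23 of them on chromosome 13. For snRNA genes there were 32 peaks against 9.53 (3.36-fold), for microRNA genes 30 against 10.0 (2.99-fold), for snoRNA genes 52 against 11.9 (4.35-fold) and for lncRNA genes 377 against 229.7 (1.64-fold), each with an adjusted p of 0.0024. When each peak was moved by 20 to 500 kb instead, the tRNA excess was 3.93-fold, and without dense regions the snoRNA excess was 1.78-fold. Pseudogenes had 131 peaks against 133.7 in the shuffles (adjusted permutation p = 0.887), and against 160.7 when peaks were moved by 20 to 500 kb, a deficit (0.815-fold, adjusted permutation p = 0.014).

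Some dense regions overlapped genes of the nucleolus and the ribosome, examples that were picked after the data were seen and not tested as a group. The region at Npm1, which encodes the nucleolar protein nucleophosmin, had 13 peaks within 10.0 kb (chromosome 11, 33148383 to 33158426), that at Rps20 had 11 (chromosome 4, 3818036 to 3834144), and that at Ncl, which encodes nucleolin, and the snoRNA genes Snora75 and Snord82 had 9 (chromosome 1, 86342397 to 86359412). A dense region of 12 peaks on chromosome 7 (3191970 to 3222478) overlapped Mir290a to Mir295, microRNAs typical of ES cells, and Nlrp12. The largest dense region after that of the tagged gene held 73 peaks over Gm15319 on chromosome 8 (20321633 to 20376657), and another held 27 on chromosome 9 (3000145 to 3038103) with no gene in it. Whether such regions are repeated sequence with raised signal, rather than sites of TOBF1, was not examined. Of the 64 dense regions on chromosomes, 11 held a snoRNA gene, 5 a ribosomal protein gene and 2 a core pluripotency gene (Zfp42 and Esrrb).

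The density of peaks differed between chromosomes. Chromosome 13 had 6.90 peaks per Mb and chromosome 1 had 6.0, while the median of the 19 autosomes was 4.55. Chromosome X had 1.64 per Mb without the tagged-gene region, which is 0.373 of the median autosome without dense regions, and chromosome Y had 0.209. The number of copies of each chromosome in these cells and how well reads map to it were not examined. A lower density therefore need not mean less binding.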
